A study of Mus musculus with 24 samples.

How the data were processed

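RNA of P19 mouse embryonal carcinoma cells was hybridised to Affymetrix Mouse Gene 1.0 ST arrays from 200 ng of total RNA per array with the Ambion WT Expression Kit, per the labels' protocols. The table used holds deposited log2 expression values of 35556 probesets on 24 arrays. The submitters' processing notes name Affymetrix Expression Console and limma, and the normalization and summarisation method is not given in the sources used here. Deposited values ran from 2.144 to 14.6 and array medians from 6.423 to 6.655, so the arrays were taken as normalized to each other and no further scaling was applied in the values reported. The probe annotation lists 23410 probesets, of which 21789 have 1 gene symbol and 1621 have several, and 12146 are not listed. Listed probesets were tested, genes were named from those with 1 symbol, which cover 19938 genes, and a gene with more than 1 probeset was represented by the one with the highest mean. Setx is not among the annotated genes and was not analysed here. The RefSeq gene table of assembly GRCm38.p6 was used for older symbols and for which genes neighbour each other.

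The labels give 6 groups of 2 biological replicates, each hybridised to 2 arrays as technical replicates. Technical arrays were averaged, which left 12 samples. One linear model with a mean per group was fitted to all 12 with limma version 3.58.1 in R version 4.3.3 (lmFit, contrasts.fit and eBayes), with 6 residual degrees of freedom shared by all groups, since 2 samples per group alone give a poor estimate of the spread. Tests were two-sided and Benjamini-Hochberg adjusted over all tested probesets, and a probeset passed at an adjusted p under 0.05. There were 7 comparisons of groups and 2 interactions.

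Of 28 gene lists, each was tested with camera (preset inter-gene correlation 0.01, adjusted over the lists within a comparison), with camera with an estimated correlation and with fry. Counts adjusted over the list alone used the members' p-values only. Named genes were the 8 highest and 8 lowest by log2 change among those that passed with both replicates of one group beyond both of the other, the 3 with the smallest p per direction where fewer passed, 5 per direction for an interaction, and up to 4 members with the smallest p of each list that was called or had at least 3 members past the threshold. A part of these genes is described in the text, chosen for known function. The groups, tests, lists and naming rule were set before the data were examined. The Y-linked genes, Meg3, Igf2r, Nanog and Dlk1 were chosen after their values were seen.

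The model was tested on simulated data for the comparison of knockdown and control cells without retinoic acid: with 200 of 23410 probesets changed in each of 5 draws, 81.4% of 2-fold and 97.2% of 4-fold changes were recovered, with 10.6 false calls on average, and a list shifted by 0.5 log2 units was called in 5 of 5 draws. The simulated noise was normal, independent between probesets, and had the same SD in all groups. In the data the control replicates differed more (SD of the difference 0.353 without and 0.426 with retinoic acid) than those of the other lines (0.18 to 0.276). Members of a list may also vary together, so these figures hold for the simulated setting only.

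Correlations between comparisons were computed across probesets, with 100 simulations of unchanged groups against the same controls, and 100 in which same-numbered samples deviate together between groups as in the data. The alternatives were a replicate block, all 24 arrays with the biological replicate as a random block (duplicateCorrelation, consensus correlation 0.36), 1 array per replicate, quantile normalization, median centring, leaving out the dim 40% of probesets, every probeset of the table, eBayes with trend and robust settings, only the groups compared, the mean of all probesets of a gene for the lists, and leaving out each replicate. A fit that leaves 1 sample in a group assumes that it varies like the other groups. Leaving out array 1 of knockdown cells with retinoic acid, replicate 1, leaving out control replicate 2 in both conditions, a replicate block within each line, and the simulation with samples that deviate together were added after seeing the data.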

Results

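P19 cells are mouse embryonal carcinoma cells that take a neural course when treated with retinoic acid. RNA was measured in 3 lines of them: control cells, cells with a short hairpin RNA against Setx, called knockdown cells here, and cells transfected with human wild-type Setx, called human Setx cells here. Setx encodes senataxin, an RNA and DNA helicase linked to transcription termination. Each line was taken with and without retinoic acid on day 1, which made 6 groups of 2 biological replicates, and each biological replicate was hybridised to 2 arrays, 24 in all. Setx itself has no entry in the probe annotation used, so its level was not analysed here and the knockdown was not checked at the RNA level.

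The 2 arrays of a biological replicate correlated at 0.9818 to 0.9958 across probesets. The SD of their difference had a median of 0.2776 log2 units and was highest, at 0.4723, in replicate 1 of knockdown cells with retinoic acid. The 2 control replicates differed from each other in sex-linked and imprinted genes in both conditions. Eif2s3y, a translation factor gene on the Y chromosome, stood at 9.76 in control replicate 1 and 4.46 in control replicate 2 without retinoic acid, and at 9.79 and 4.35 with it. The Y-linked genes Uty and Kdm5d were likewise lower in control replicate 2, by 5.05 and 3.66 log2 units without retinoic acid. All 3 genes were above 8.3 in every sample of the other lines, so the means of the control group mix 2 different states for them. Usp9y, also Y-linked, stood at 7.9 in control replicate 1 and 4.28 in control replicate 2, and lay between 4.28 and 4.51 in all 4 knockdown samples. The imprinted RNA gene Meg3 ran the other way in the control cells, with 6.4 in replicate 1 and 9.9 in replicate 2. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples. The number of arrays limits the precision of every value.

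**Figure D1:**
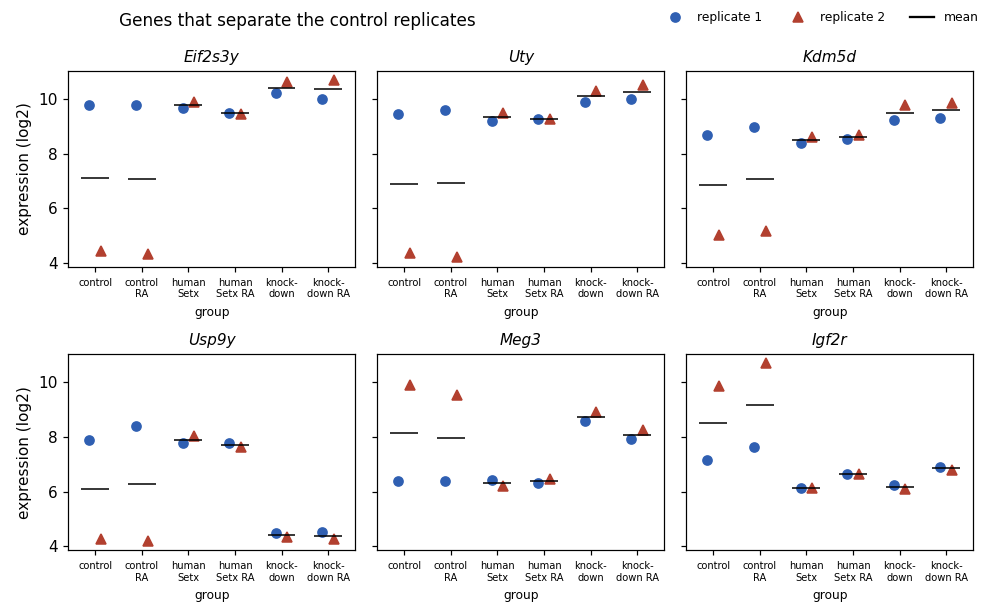
Expression (log2) of 6 genes in the 12 biological replicates, by group; circles are replicate 1, triangles replicate 2 and lines the mean of both. Eif2s3y, Uty, Kdm5d and Usp9y sit between 4.18 and 5.17 in control replicate 2, and Usp9y also sits between 4.28 and 4.51 in the knockdown cells.

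The first comparison asked how knockdown cells differed from control cells without retinoic acid. Peg3, an imprinted zinc finger gene, was 44-fold lower (log2 change -5.46, SE 0.271, n = 2 per group, limma adjusted p = 4.35e-05), with a level of 5.96 ± 0.105 (SD, n = 2) against 11.4 ± 0.634 in control cells. Casp8, the initiator caspase of death receptors, was 24.4-fold lower (-4.61, SE 0.394), and Sall4, a transcription factor of pluripotent cells, was 23.9-fold lower (-4.58, SE 0.4). Gstp1 (-5.09), the mitochondrial carrier gene Slc25a13 (-4.47), the thyrotropin-releasing hormone gene Trh (-4.37) and the chloride channel gene Cftr (-3.96) were also lower, and the Gstp1 value is uncertain because it has a close paralog. In the other direction, Dcn, which encodes the matrix proteoglycan decorin, was 20-fold higher (4.32, SE 0.474) and the transcriptional cofactor gene Cited1 18-fold higher (4.17, SE 0.208). Slco4c1 (3.62), Abca4 (3.62) and Zfp640 (3.96, SE 0.948) were higher as well. Zfp640 belongs to a large zinc finger family and differed between the control replicates, by 2.45 log2 units, and its adjusted p of 0.0351 became 0.172 without replicate 1 of the knockdown cells.

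Genes of several developmental groups changed without retinoic acid, in both directions. In this comparison 2107 of 23410 probesets passed, and 1878 of 19938 genes. Camera called none of the lists in this paragraph or the next, and the share of retinoic acid response genes that passed was close to that of all genes. Among 25 measured genes of the retinoic acid response, 3 rose and none fell (4 and 0 adjusted over the list alone). They were the homeobox gene Meis1 (2.48), the retinoic acid carrier gene Crabp2 (2.21) and the receptor gene Rarb (1.03), in cells to which no retinoic acid had been added. Of 34 pluripotency genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone); besides Sall4, Foxd3 (-2.71) and the DNA methyltransferase gene Dnmt3b (-1.81) fell, whereas Fbxo15 rose (2.90). Of 29 neural progenitor genes 3 rose, with Zic1 at 3.04, and 1 fell, Zic2 at -1.88 (4 and 1 adjusted over the list alone). Of 28 genes of neuronal structure 4 rose and 4 fell (5 and 4 adjusted over the list alone), among them Ncam1 (1.09) and Nefm (-2.06). The Ncam1 change was 0.70 without control replicate 1 without retinoic acid. Ncam1 lost its call in 3 fits that left out a replicate and Nefm in 1. Axon guidance genes also went both ways, with 3 higher and 5 lower of 36 (6 and 7 adjusted over the list alone), as for the ephrin gene Efnb1 (2.94) and the semaphorin gene Sema6a (-2.88). Their median was 0.0493 while their mean, -0.0896, and the test pointed down.

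Signalling and cell cycle genes were among those called as well. Of 35 genes of FGF signalling 2 rose and 5 fell (3 and 8 adjusted over the list alone), with Fgfr2 at 1.11 and the feedback inhibitor Spry4 and the early response gene Egr1 at -2.42 and -1.73. In the Notch list of 21 genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone), including the ligand gene Dll1 (1.66) and the target Hes1 (-1.11). Of 23 mesoderm and primitive streak genes 1 rose, Twist1 (1.28), and 2 fell, Fgf8 (-1.04) being one (1 and 2 adjusted over the list alone), though Fgf8 lost its call in 9 of the 12 fits that left out a replicate (adjusted p = 0.175 without replicate 1 of the knockdown cells). Twist1 lost its call in 3 such fits. Of 31 cell cycle genes 3 rose and 7 fell (3 and 9 adjusted over the list alone). Cdkn2a, which encodes inhibitors of the cell cycle, was 5.04-fold higher (2.33, SE 0.163, adjusted p = 0.000131), while the cyclin genes Ccnd1 (-2.72) and Ccne1 (-1.18) fell. Among 22 markers of fibroblasts and mesenchyme, a cell type the cultures could hold, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with Pdgfrb at 1.72, Postn at 1.65 and the smooth muscle gene Cnn1 at -2.60.

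Senataxin acts with factors of transcription termination and RNA surveillance. Of 30 genes of that list none rose and 4 fell (1 and 4 adjusted over the list alone): Ctdp1 (-0.75), the exosome genes Exosc2 (-0.83) and Exosc5 (-0.52), and Smn1 (-0.55). Exosc5 lost its call in 10 of the 12 fits that left out a replicate, Exosc2 in 3 and Smn1 in 2, while Ctdp1 kept it in all. This was the single list of 28 that camera called without retinoic acid (median -0.195, adjusted p = 0.0104), with adjusted p = 0.94 with an estimated correlation. In all, 2107 of 23410 probesets passed, 1145 higher and 962 lower, and 606 of them changed at least 2-fold. The higher share of 54.3% became 41.9% under median centring. The count fell to 548 and 752 without replicate 1 or 2 of the knockdown cells, to 1334 and 1204 without replicate 1 or 2 of the control cells, and to 986 with the compared groups alone, and 15 of the 41 genes named for this comparison lost their call in at least 1 fit that left out a replicate.

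**Figure D2:**
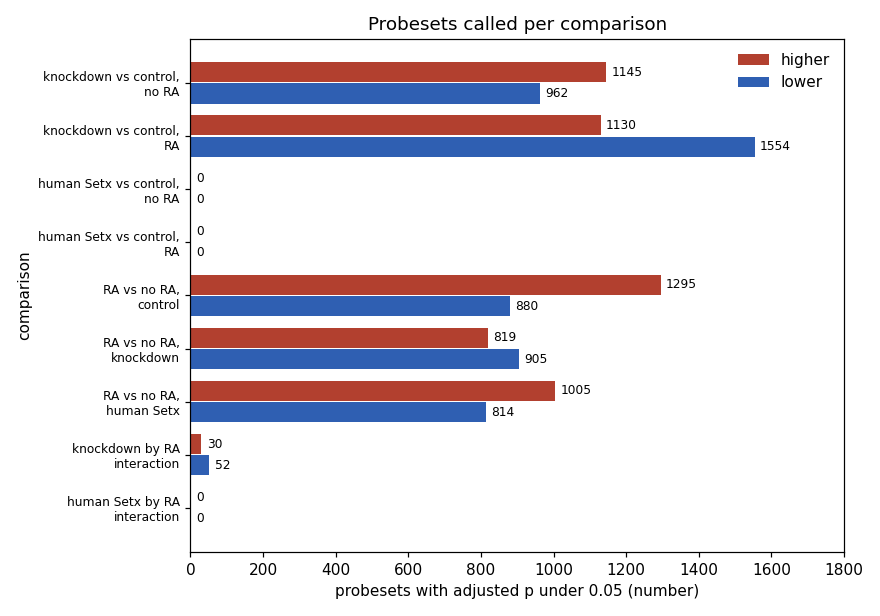
Number of probesets with a limma adjusted p under 0.05 in each of the 9 comparisons, higher in red and lower in blue, out of 23410 tested. The knockdown and retinoic acid comparisons hold 814 to 1554 calls per direction and the interaction for knockdown cells 30 and 52. The comparisons of human Setx with control cells and the interaction for human Setx cells hold 0.

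With retinoic acid, the knockdown cells again differed from control cells in many genes. Peg3 was 61.1-fold lower (-5.93, SE 0.271, n = 2 per group, limma adjusted p = 1.39e-05), at 5.91 ± 0.202 (SD, n = 2) against 11.8 ± 0.347. Casp8 (-5.46), Gstp1 (-5.81), Cftr (-4.47), the imprinted gene Impact (-4.21), the Rac activator gene Dock1 (-4.02), Adal (-3.99) and Sall4 (-3.78) were lower too. Thbs1, which encodes the matrix protein thrombospondin, was 13.4-fold higher (3.75, SE 0.217, adjusted p = 4.12e-05) and the carbonic anhydrase gene Car7 12.6-fold higher (3.66, SE 0.198). Hoxb13 (3.21), the matrix gene Ogn (3.14), Tbx15 (3.14), Zic1 (2.90) and the integrin gene Itgb3 (2.83) were higher, and Zfp640 (3.69, adjusted p = 0.0385, and 0.139 without replicate 1 of the knockdown cells) was higher with the spread given above.

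Of 29 neural progenitor genes 10 rose, 1 fell and 18 did not pass in this comparison (13 higher and 2 lower adjusted over the list alone). Neurog1, a proneural factor, was 5.36-fold higher (2.42, SE 0.333), and Pou3f1 (1.42) and Sox11 (1.16) were higher too. The list passed with camera (median 0.194, adjusted p = 0.011) and with fry (adjusted p = 0.0425), with adjusted p = 0.507 with an estimated correlation. Of 23 posterior Hox genes 4 rose (4 adjusted over the list alone), including Hoxd8 (1.72) and Hoxd10 (0.58), and the list was called (adjusted p = 0.0109; adjusted p = 0.857 with an estimated correlation). Hoxd10 lost its call in 3 fits that left out a replicate, and with 1 array per replicate (0.43, limma adjusted p = 0.102). The neuronal genes Ncam1 (1.30) and Map2 (1.60) were among 3 of 28 that rose, with 1 lower (3 and 3 adjusted over the list alone). Without control replicate 1 with retinoic acid the Map2 change was 1 log2 unit. Map2 lost its call in 3 fits that left out a replicate and Ncam1 in 1. For axon guidance, 2 of 36 rose and 1 fell (1 and 1 adjusted over the list alone), with the guidance ligand gene Slit2 at 1.05 and its receptor gene Robo2 at -2.59; the median was 0.00147 while the mean, -0.0578, and the test pointed down. Of 25 genes of the retinoic acid response 1 rose and 3 fell (1 and 6 adjusted over the list alone), among them the retinol receptor gene Stra6 (-0.92) and Aldh1a2 (-1.13), which encodes an enzyme that makes retinoic acid. The Aldh1a2 change was -0.66 without control replicate 2 with retinoic acid, and its call was lost in 3 fits that left out a replicate.

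Of the termination and RNA surveillance list 6 of 30 fell and none rose (12 and 1 adjusted over the list alone), with Exosc5 at -0.84 and Ctdp1 at -0.70. The list was called (median -0.289, adjusted p = 0.00232), with adjusted p = 0.857 with an estimated correlation. Of 18 cholesterol synthesis genes 1 fell, Idi1 at -1.08 (1 adjusted over the list alone). The list was called (camera adjusted p = 0.011), with adjusted p = 0.949 with an estimated correlation. Idi1 lost its call in 4 fits that left out a replicate. It also lost it without array 1 of knockdown cells with retinoic acid, replicate 1 (-0.875, limma adjusted p = 0.0594). Of 18 endothelial and blood markers 3 fell (3 adjusted over the list alone), the receptor genes Kdr (-2.67) and Eng (-1.40) and the adhesion gene Esam (-1.21), and this list was called as well (adjusted p = 0.011; adjusted p = 0.932 with an estimated correlation). Pluripotency genes went both ways, with 2 of 34 higher and 3 lower (2 and 4 adjusted over the list alone), as for Otx2 (2.15) and Dnmt3b (-1.53). Kdr and Otx2 each lost the call in 2 fits that left out a replicate. In the mesoderm list, Bmp4 (1.92) was among 2 that rose and Lhx1 (-2.79) was the 1 that fell, of 23 (2 and 1 adjusted over the list alone), with a median of -0.17 and a mean of -0.00339 while the test pointed up. Dll1 (2.83-fold) was 1 of 2 Notch genes that rose, against 1 that fell, of 21 (2 and 1 adjusted over the list alone). In the cell cycle list 1 of 31 rose and 5 fell (1 and 6 adjusted over the list alone), with Cdkn2a at 1.89, Ccnd1 at -1.48 and Ccne1 at -1.37. Of 22 fibroblast and mesenchyme markers 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Dcn at 2.79, Pdgfrb at 1.39 and Cnn1 at -2.41.

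The count with retinoic acid was 2684 probesets, 1130 higher and 1554 lower, of which 714 changed at least 2-fold. The higher share of 42.1% became 24.9% under median centring. The count was 1042 and 838 without replicate 1 or 2 of the knockdown cells, 1773 without replicate 1 of the control cells, and 151 with the compared groups alone, and 14 of the 44 genes named lost their call in at least 1 fit that left out a replicate.

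Knockdown changes without and with retinoic acid rested on different control samples, and their log2 changes correlated at 0.687 across probesets, which are not replicates. Same-numbered replicates deviated together between conditions, and unchanged groups simulated with such replicates gave a correlation of 0.335 and a covariance of 0.0123, against an observed covariance of 0.137. Of the probesets called in both conditions 415 were higher in both, against 55.27 for independent lists, 655 were lower in both, against 63.86, and 12 went opposite ways, against 122.4. At least 2-fold changes in the same direction in both conditions were found in 276 probesets, 133 higher and 143 lower, and 83% of these met the same criteria without control replicate 2.

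**Figure D3:**
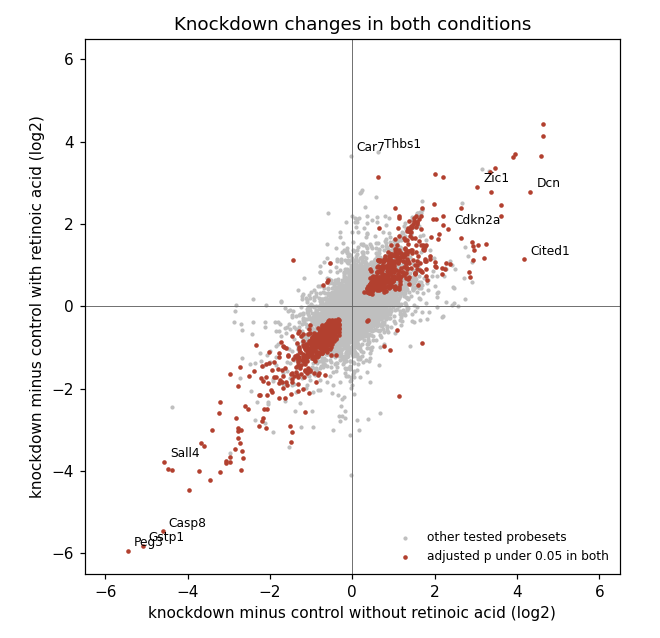
Change of each tested probeset in knockdown minus control cells (log2) without retinoic acid (horizontal) and with it (vertical); red points passed the limma test in both conditions. Peg3, Gstp1, Casp8 and Sall4 lie far to the lower left and Dcn and Zic1 to the upper right, while Car7 and Thbs1 changed past the threshold with retinoic acid alone.

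Human Setx cells were compared with the same control cells, and none of the annotated probesets passed in either condition. With every probeset of the table fitted 14 and 12 passed. Of these, 11 were without annotation and higher in both conditions, by 2.69 to 3.42 log2 units, and by less and short of the threshold in knockdown cells. The smallest p-values without retinoic acid belonged to Slitrk3 (log2 change 1.13, SE 0.126, limma adjusted p = 0.113), the kinase gene Mapkapk2 (-1.46, adjusted p = 0.113), both with adjusted p = 0.0322 with every probeset, and the sugar metabolism gene Galm (-1.48, adjusted p = 0.14). With retinoic acid they belonged to Galm (-1.99, SE 0.196, adjusted p = 0.0766), the adenylyl cyclase gene Adcy3 (-1.33) and Upk3bl (0.83). Galm passed with retinoic acid in 9 of 23 other fits, among them that without control replicate 1 (adjusted p = 0.0049) and that without control replicate 2 (adjusted p = 0.0292). Zic1 had a change of 1.94 without and 2.06 with retinoic acid, with adjusted p-values of 0.378 and 0.358. By limma with averaged arrays the count was 0 in both conditions, with 1240 and 1308 probesets at an unadjusted p under 0.05, whereas limma with all arrays and the biological replicate as a random block called 106 and 139. Without control replicate 1 of the condition, 75 and 368 probesets passed.

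Several lists were called in human Setx cells although none of their members passed over all probesets. Without retinoic acid camera called Wnt signalling genes (median 0.295, adjusted p = 0.000159), snoRNA genes (0.193, 1.17e-05), replication-dependent histone genes (0.109, 0.000215), axon guidance genes (0.101, 0.0122) and neural progenitor genes (0.000948, 0.0302) as higher. Cholesterol synthesis genes (-0.44, 0.000159) and genes of the integrated stress and unfolded protein response (-0.234, 0.0166) were called lower, and all 7 had adjusted p = 0.802 with an estimated correlation. Adjusted over the list alone, 3 neural progenitor genes, 1 axon guidance gene, Slit2 (0.91), and 1 Wnt gene passed. With retinoic acid the posterior Hox genes (0.174, 1.68e-06), for which 4 members passed adjusted over the list alone, and the neural progenitor genes (0.208, 0.00101), with 1, were called higher, both with adjusted p = 0.256 with an estimated correlation. Hoxb7 (0.58) and Hoxa10 (0.65) had the smallest p-values in the Hox list. Termination and RNA surveillance genes (-0.0817, 0.00522), cholesterol synthesis genes (-0.307, 0.000304) and endothelial and blood markers (-0.365, 7.23e-05) were called lower, each with adjusted p = 0.936 with an estimated correlation.

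The changes in human Setx cells without and with retinoic acid correlated at 0.383 across probesets, and at 0.0692 without control replicate 2 with retinoic acid, 0.195 without control replicate 2 without it, and 0.216 without replicate 1 of human Setx cells with it. Unchanged groups simulated with replicates that deviate together between groups gave 0.419, with a covariance of 0.013 against 0.0192 observed, so the correlation of 0.383 alone does not show an effect of human Setx. The simulation used the residual SD over all groups, and the control replicates differed by more than that. Knockdown and human Setx changes shared their control samples and correlated at 0.15 without and 0.246 with retinoic acid, where unchanged groups simulated against shared controls gave 0.499 and 0.5. The covariance was 0.0145 and 0.0254, against a simulated 0.0215. With replicates that deviate together the simulated correlations were 0.524 and 0.272 and the covariances 0.0191 and 0.00846. Between conditions, where no control sample is shared, the correlations were 0.103 and 0.07, against 0.312 and 0.0851 with such replicates (covariance 0.0101 and 0.00709, against 0.00956 and 0.00315), and both changed sign when a control replicate with retinoic acid was left out (-0.00511 without replicate 1 and -0.0746 without replicate 2). Without control replicate 1 the correlations with shared controls were 0.408 and 0.472, and without control replicate 2 they were 0.256 and 0.456.

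Retinoic acid changed the known target genes in control cells by large factors. Cyp26a1, which encodes the enzyme that degrades retinoic acid, rose 31.3-fold (log2 change 4.97, SE 0.507, n = 2 per group, limma adjusted p = 0.00103), and the homeobox genes Meis1 (4.93) and Meis2 (4.92) and the carrier gene Crabp2 (4.92) rose to a similar degree. The receptor gene Rarb rose 22-fold (4.46, SE 0.111, adjusted p = 4.6e-07), and Stra6 rose by 2.77 log2 units. All 14 anterior Hox genes rose (14 adjusted over the list alone), with Hoxa5 at 4.70, Hoxb2 at 4.63 and Hoxb1 at 4.49, and the casein gene Csn3 rose by 4.61. Among the genes that fell most were the coreceptor gene Tdgf1 (-4.32), the probesets annotated to the precursor genes Mir302c (-3.71) and Mir302a (-3.50), Otx2 (-3.48), Utf1 (-3.31), the kinase gene Pim2 (-3.30) and the activin antagonist gene Fst (-3.29). Tdgf1 had an SD of 2.5 between the control replicates with retinoic acid, where it stood at 9.38 and 5.84, and its adjusted p of 0.0493 became 0.194 without control replicate 2.

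By list, 17 of 25 retinoic acid response genes rose and none fell in control cells (19 and 2 adjusted over the list alone), with a median of 1.82 (camera adjusted p = 2.28e-16). This list kept its call with an estimated correlation in all 3 lines (adjusted p = 0.00218 in control, 0.00363 in knockdown and 0.00215 in human Setx cells), and it was the only list of the 28 to do so in any of the 9 comparisons. The anterior Hox list had a median of 2.65 (adjusted p = 7.21e-19), with adjusted p = 0.124 with an estimated correlation. Of 34 pluripotency genes 3 rose and 7 fell (3 and 9 adjusted over the list alone), with Dnmt3b at -2.74 and Foxd3 at -2.63 but Lefty2 at 3.58 and Tbx3 at 2.26; 24 did not pass, and the list was not called (adjusted p = 0.0526, and 0.85 with an estimated correlation). Among 36 axon guidance genes 6 rose and 3 fell (8 and 3 adjusted over the list alone), with Plxna2 (4.33), Robo2 (3.13) and Slit2 (2.18) higher, and the list was called (adjusted p = 0.000414; adjusted p = 0.802 with an estimated correlation). Of 29 neural progenitor genes 4 rose, including Pax6 (2.26) and Gbx2 (2.83-fold), and 1 fell (4 and 1 adjusted over the list alone). Pax6 lost its call in 3 fits that left out a replicate (adjusted p = 0.108 without control replicate 2 without retinoic acid), and its change was 1.37 without control replicate 2 with retinoic acid. Of 23 targets of p53, a stress-activated transcription factor, 7 rose and 2 fell (10 and 2 adjusted over the list alone), with Trp53inp1 at 2.13 and Sesn2 at 1.01, and the list was called (adjusted p = 0.00232; adjusted p = 0.484 with an estimated correlation).

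In FGF signalling 5 of 35 genes rose and 6 fell (6 and 12 adjusted over the list alone), with Fgfr2 at 2.21 and the feedback inhibitors Spry4 and Spry2 at -2.98 and -1.72. Of 21 Notch genes 3 rose, Dll1 (1.81) among them, and 1 fell (4 and 2 adjusted over the list alone). Of 23 mesoderm genes 4 rose and 2 fell (4 and 4 adjusted over the list alone), and Lhx1 rose by 3.06. Of 24 Wnt signalling genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), Ccnd1 at -1.94 being one, and their median of -0.127 and mean of -0.0757 were negative while the test pointed up. Of 18 endothelial and blood markers 2 rose (2 adjusted over the list alone), with Kdr at 2.75, and the list had adjusted p = 0.0482, with adjusted p = 0.828 with an estimated correlation. Kdr lost its call without control replicate 1 or 2 without retinoic acid (adjusted p = 0.0617 and 0.0763), and its change was 1.76 (adjusted p = 0.0807) without control replicate 2 in both conditions. In all 2175 probesets passed in control cells, 1295 higher and 880 lower, 664 of them by at least 2-fold, whereas quantile normalization gave 1046 in each direction. The count was 1434 and 984 without replicate 1 or 2 of control cells without retinoic acid, 895 without control replicate 2 with it, 1382 without either replicate of human Setx cells without it, 1 with the compared groups alone, and 800 without control replicate 2 in both conditions. Of the 35 genes named for this comparison 4 lost their call in at least 1 fit that left out a replicate: Tdgf1, Pax6, Kdr and Fst (adjusted p = 0.0677 without control replicate 1 without retinoic acid).

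In knockdown cells retinoic acid raised Csn3 (5.78, SE 0.51), Lefty2 (5.35, SE 0.419), Hoxa5 (5.31, SE 0.219), Cyp26a1 (5.06, SE 0.507), Meis2 (4.30) and Rarb (3.93), and lowered Mir302c (-3.65), Utf1 (-3.09) and Dnmt3b (-2.46), all past the limma threshold with n = 2 per group. Of 25 response genes 15 rose and 1 fell (17 and 3 adjusted over the list alone), and 12 of 14 anterior Hox genes rose (13 adjusted over the list alone), with medians of 1.29 and 2.92; the Hox call had adjusted p = 0.0965 with an estimated correlation. Of 29 neural progenitor genes 8 rose and none fell (9 and 3 adjusted over the list alone), among them Neurog1 (2.51), Pou3f1 (1.86) and Sox11 (1.64), and the list was called (adjusted p = 0.00013; adjusted p = 0.0965 with an estimated correlation). For axon guidance 7 of 36 rose and 2 fell (9 and 2 adjusted over the list alone), with Slit2 at 3.77 (list adjusted p = 1.34e-05; adjusted p = 0.387 with an estimated correlation). Of 21 Notch genes 7 rose and 1 fell (9 and 1 adjusted over the list alone; list adjusted p = 0.000255, and adjusted p = 0.387 with an estimated correlation). Among 23 p53 targets 3 rose, Plk2 at 3.16 among them, and 2 fell (4 and 2 adjusted over the list alone). Of 26 interferon response genes 2 rose (2 adjusted over the list alone), with Oasl2 at 2.63 (list adjusted p = 0.0312; adjusted p = 0.676 with an estimated correlation). Posterior Hox genes were called higher, with 8 of 23 past the threshold and none lower (9 and 1 adjusted over the list alone; list adjusted p = 1.07e-05, and adjusted p = 0.195 with an estimated correlation). Called lower were the termination and RNA surveillance genes (4 of 30, adjusted p = 0.00306), cholesterol synthesis genes (1 of 18, 0.000608) and genes of the oxidative stress response (1 of 18, 0.0158), with 6, 1 and 1 adjusted over the list alone. These 3 had adjusted p = 0.586, 0.781 and 0.387 with an estimated correlation. The count was 1724 probesets, 819 higher and 905 lower, 613 by at least 2-fold. The direction of the majority depended on the replicates, with 244 higher and 206 lower without replicate 2 without retinoic acid, and 436 and 377, and 280 and 215, without replicate 1 or 2 with it. Of the 16 genes named 4 lost their call in at least 1 such fit: Meis2 (adjusted p = 0.0607), Mir302c (0.057) and Plk2 (0.0803) without replicate 2 without retinoic acid, and Utf1 (0.066) without replicate 2 with it. The count was 697 and 450 without replicate 1 or 2 of knockdown cells without retinoic acid, 813 and 495 without replicate 1 or 2 with it, and 2850 without control replicate 2 in both conditions.

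Human Setx cells answered retinoic acid with higher Hoxb2 (5.04, SE 0.268), Hoxa5 (4.99, SE 0.219), Rasgrp3 (4.63), Cyp26a1 (4.58, SE 0.507) and Plxna2 (4.44), and with lower Tdgf1 (-4.51), Mir302a (-4.49), Mir302c (-4.48) and Spry4 (-3.27), by limma with n = 2 per group. The Tdgf1 adjusted p of 0.0468 became 0.242 without replicate 2 of human Setx cells with retinoic acid, and it was the 1 of 9 named genes to lose its call in a fit that left out a replicate. Of 25 response genes 15 rose and 1 fell (19 and 1 adjusted over the list alone), and all 14 anterior Hox genes rose (14 adjusted over the list alone; adjusted p = 0.0895 with an estimated correlation). Of 23 posterior Hox genes 7 rose (12 adjusted over the list alone; list adjusted p = 2.59e-05, and adjusted p = 0.299 with an estimated correlation). FGF signalling genes fell in 9 of 35 cases and rose in 5 (14 and 6 adjusted over the list alone; list adjusted p = 0.00396, and adjusted p = 0.412 with an estimated correlation). Of 51 snoRNA genes 5 fell (6 adjusted over the list alone; list adjusted p = 0.000227, and adjusted p = 0.789 with an estimated correlation). Of 30 termination and RNA surveillance genes 6 fell (14 adjusted over the list alone; list adjusted p = 5.51e-05, and adjusted p = 0.472 with an estimated correlation). Axon guidance genes (7 of 36 higher, 3 lower, and the same adjusted over the list alone; adjusted p = 0.012) and Notch genes (4 of 21 higher, 2 lower, 9 and 2 adjusted over the list alone; 0.0322) were called higher, with adjusted p = 0.671 and 0.672 with an estimated correlation. Endoderm genes (4 of 22 higher, 4 adjusted over the list alone; 0.00396) and interferon response genes (3 of 26 higher, 5 adjusted over the list alone; 0.00277) were called higher too, both with adjusted p = 0.472 with an estimated correlation. The count was 1819 probesets, 1005 higher and 814 lower, 674 by at least 2-fold. It was 455 and 473 without replicate 1 or 2 of human Setx cells without retinoic acid, 564 without replicate 2 with it, and 3120 without control replicate 2 in both conditions.

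**Figure D4:**
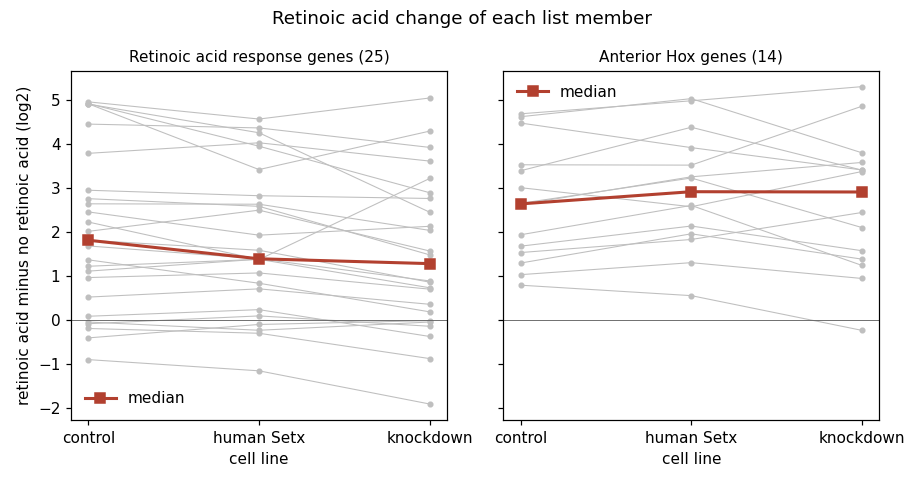
Change with retinoic acid (log2) of each measured gene of the retinoic acid response (25 genes) and anterior Hox (14 genes) lists in the 3 lines; grey lines join the values of a gene and red squares mark medians. The median of the response list is 1.82 in control, 1.4 in human Setx and 1.29 in knockdown cells, and that of the anterior Hox list 2.65, 2.92 and 2.92.

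Retinoic acid changes in control and human Setx cells correlated at 0.85 across probesets, those in control and knockdown cells at 0.683, and those in knockdown and human Setx cells at 0.639. Unchanged groups with replicates that deviate together gave 0.212, 0.107 and -0.00279. Of the probesets called in both control and knockdown cells 415 rose in both, against 45.31 for independent lists, 356 fell in both, against 34.02, and 8 went opposite ways.

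Whether the retinoic acid change itself differed from that of control cells was tested as an interaction. In knockdown cells it was larger for Car7 (difference 3.70 log2 units, SE 0.281, limma adjusted p = 0.00591), Thbs1 (3.12, SE 0.307, adjusted p = 0.00725), Skida1 (2.86), Glrx (2.75), which encodes the thiol enzyme glutaredoxin, and Itgb3 (2.60). It was smaller for ccdc198 (-4.06, SE 0.331, adjusted p = 0.00591), Kynu (-3.32), Robo2 (-3.26), Adgrf5 (-3.16) and Capn5 (-3.13). Among listed genes, Slit2 (1.59), Sema6a (2.49), Lhx1 (-2.50) and Stra6 (-1.28) passed, while Meis1 (-2.03, adjusted p = 0.0707) and Crabp2 (-2.46, adjusted p = 0.109) did not. The retinoic acid response list was called lower (median -0.46, adjusted p = 0.000159), with 1 of 25 members past the threshold (3 adjusted over the list alone), fry adjusted p = 0.0219, and adjusted p = 0.0651 with an estimated correlation. In all 82 probesets passed, 30 higher and 52 lower, but 30 higher and 19 lower without replicate 1 of knockdown cells with retinoic acid. The count was 2 without replicate 2 of knockdown cells in either condition, 22 and 49 without their replicate 1 without and with retinoic acid, 282 and 132 without control replicate 1 or 2 with retinoic acid, 26 and 54 without a replicate of human Setx cells without and with it, and 9 with the compared groups alone. Of the 14 named genes that passed, 13 lost the call in at least 1 fit without a replicate, Car7 being the exception; Itgb3 and Sema6a lost it in 10 of the 12 such fits and Stra6 in 9.

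For human Setx cells limma called 0 probesets in the interaction, with 1059 at an unadjusted p under 0.05, 0 with all arrays and a random block, and 52 without control replicate 1 with retinoic acid. Genes of DNA damage repair, of hypoxia and glycolysis, and of ribosomal proteins were called as lists in none of the 9 comparisons.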

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

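The tests of noise that is independent between arrays, of divergence between cell lines, of the share of change left by scaling and of progress with retinoic acid only were chosen only after the results were seen.

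The retinoic acid change differed between knockdown and control cells in 82 probesets by the interaction test. The largest differences were those of Car7 (3.70), Thbs1 (3.12), Skida1 (2.86), Glrx (2.75), Itgb3 (2.60), ccdc198 (-4.06), Kynu (-3.32), Robo2 (-3.26), Adgrf5 (-3.16) and Capn5 (-3.13). A single divergent array does not account for them, since without array 1 of knockdown cells with retinoic acid, replicate 1, 105 probesets passed, 72 of the 82 among them, and all 10 of these genes kept their call. Whether all target genes responded more weakly cannot be decided. The median change of the anterior Hox genes in knockdown cells was 1.1 times that in control cells (95% bootstrap interval 0.792 to 1.41). For the 429 genes raised at least 2-fold by retinoic acid in human Setx cells the ratio was 0.646 (0.603 to 0.706). Both intervals resample genes, which are not replicates, and the first still allows a weaker response. The 429 were chosen in human Setx cells, whose same-numbered samples deviate with those of control cells. With retinoic acid these deviations correlated at 0.398 with control and -0.0746 with knockdown cells, which favours a larger change in control cells. A difference limited to part of the target genes remains open as a hypothesis and may come from the line and not from Setx. A smaller change need not mean a lower level with retinoic acid. Meis1 and Crabp2 were already higher in knockdown cells without retinoic acid, whereas Stra6 was lower in them with it.

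Lists with a different retinoic acid change in knockdown cells by camera were the retinoic acid response (lower, adjusted p = 0.000159), posterior Hox genes (higher, 0.00618), neural progenitor genes (higher, 0.0112), mesoderm genes (higher, 0.0436), FGF signalling (higher, 0.0194), cholesterol synthesis (lower, 0.0159) and endothelial and blood markers (lower, 0.0436). None of the 7 kept its call with an estimated correlation, where the smallest adjusted p was 0.0651. In human Setx cells the lists were posterior Hox genes (higher, 7.96e-06), Wnt signalling (lower, 0.032) and endothelial and blood markers (lower, 0.0487), with adjusted p-values of 0.636, 0.847 and 0.847 with an estimated correlation.

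At least 2-fold changes in both conditions set 276 probesets apart in knockdown cells. Gain or loss of chromosome segments as a common source was examined through the 10 nearest measured genes outside the set. Their median change was 0.00367 around lowered genes (95% bootstrap interval -0.0256 to 0.0381) and 0.0708 (0.0384 to 0.0905) around raised ones. Neighbours that belonged to the set were left out, and neighbours were not filtered by level, so the medians cannot decide the question. Losses of single genes were not tested. One divergent array is argued against because 96% were kept without it. For scaling between arrays, the lowest median share of the change left by a scaling was 0.94 (95% bootstrap interval 0.934 to 0.945). Centring moved the median change of all probesets only from 0.0247 to -0.0377 without and from 0.0471 to -0.0434 with retinoic acid. A shift of that size cannot make a 2-fold change by itself, so a uniform shift between arrays is argued against as the source of the set. The share left of changes of at least 2-fold was therefore bound to be high and adds nothing to this. Scaling stays open for members near the limits: 84.1% met the criteria under median centring and 88% under quantile normalization, short of the share set beforehand. The 44 lost under centring had a median change, the smaller of both conditions, of 1.1 (SD 0.204) before and 1.02 (SD 0.209) after. Of these, 21 fell under 2-fold and 23 lost the adjusted p alone. Divergence of the lines for reasons other than Setx cannot be told apart from an effect of the hairpin, because there is 1 knockdown line: 189 probesets differed at least 2-fold the same way in both conditions between the 2 control replicates, against 524 and 582 between knockdown replicates 1 and 2 and control replicate 1, and 433 and 425 between them and control replicate 2. Between human Setx replicates 1 and 2 and control replicate 1 the numbers were 23 and 44, and 202 and 141 with control replicate 2. Between the replicates of a line they were 13 in knockdown and 1 in human Setx cells. Control replicate 2 thus stood apart from control replicate 1 and human Setx cells alike.

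Control replicates 1 and 2 differed in both conditions. The SD of their difference was 3.01 and 3.57 times that expected from technical arrays, which compares single samples with technical noise and decides nothing. Noise that is independent between arrays is argued against, since the differences without and with retinoic acid correlated at 0.471 across probesets, a value already seen when the test was chosen. For different progress of the retinoic acid response, the correlation with the change in human Setx cells was -0.0869 without and -0.246 with retinoic acid (95% bootstrap interval -0.271 to -0.222). Both were under the 0.3 in size set beforehand, so over all probesets the difference followed the retinoic acid change only weakly. Only 1819 of 23410 probesets passed for that change, so the correlation cannot exclude different progress among genes that respond. Without retinoic acid replicate 2 also lay above replicate 1 over genes raised by retinoic acid in human Setx cells (median 0.106, 0.0661 to 0.142). It leaned below replicate 1 over those lowered (-0.0951, -0.191 to 0.046). With retinoic acid only, a response further along in control replicate 2 stays open: its median difference from replicate 1 was -0.351 (interval -0.444 to -0.279) over 207 genes lowered and 0.204 (0.137 to 0.29) over 429 raised by retinoic acid in human Setx cells, but the sign of the correlation was seen before this test.

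Probesets that the annotation does not list were outside the comparisons reported. Fitted with all others, 223 of them passed in knockdown cells without and 437 with retinoic acid, 260, 191 and 240 changed with retinoic acid in control, knockdown and human Setx cells, and 6 passed in the interaction for knockdown cells. In human Setx cells 12 passed without and 11 with retinoic acid, all higher. The 11 that passed in both conditions are consecutive in the table and rose by 2.76 to 3.42 log2 units without retinoic acid and 2.69 to 3.19 with it, among them probesets 10602277 and 10602293. In knockdown cells the same 11 were higher than in control cells by 0.798 to 1.24 log2 units without retinoic acid. With it they were higher by 0.442 to 0.661, and none passed in either condition (smallest limma adjusted p = 0.059). Probesets 10602332 and 10602341 had the same values, so the 11 are not all separate signals.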

How the results depend on the processing

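Leaving out an array of knockdown cells with retinoic acid, leaving out control replicate 2 and the replicate block within each line were chosen only after the results were seen. Of 3938 values of named genes under alternatives 3617 were counted as unchanged, 285 no longer passed and 36 passed newly. Among results that passed in the reported fit 0 changed sign, while a change of sign in the others was counted as unchanged. Of 159 named results that passed, 63 kept their call under every alternative. With all 24 arrays and a random block the counts were 4237 and 4463 for knockdown cells without and with retinoic acid, 106 and 139 for human Setx cells, 4029, 3429 and 3840 for retinoic acid in control, knockdown and human Setx cells, and 609 for the knockdown interaction. With only the groups compared they were 986 and 151 for knockdown cells and 9 for the interaction. For retinoic acid they were then 1, 2621 and 2529 in control, knockdown and human Setx cells. Fewer samples then estimate the spread, which alone does not explain why counts rose in knockdown and human Setx cells. The control replicates differed most (SD of the difference 0.353 and 0.426, against 0.18 to 0.276 in the other lines). The reported fit shares the spread over all groups, so it can understate that of comparisons with control cells. With 1 array per replicate they were 1258 for knockdown cells without retinoic acid and 1279 for retinoic acid in control cells. Every probeset gave 14 and 12 in human Setx cells, and median centring, trend and leaving out the array gave 1 with retinoic acid. Without control replicate 2 in both conditions they were 15 and 14 for human Setx cells, 800, 2850 and 3120 for retinoic acid, and 187 for the interaction.

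Left-out replicates gave ranges of 548 to 2771 and 838 to 2720 for knockdown cells, 0 to 75 and 0 to 368 for human Setx cells, 895 to 2876, 450 to 2284 and 455 to 2521 for retinoic acid in control, knockdown and human Setx cells, and 2 to 282 and 0 to 52 for the interactions of knockdown and human Setx cells. Correlations ranged from 0.584 to 0.687 between knockdown changes in both conditions, 0.0692 to 0.451 for human Setx, 0.123 to 0.408 and 0.178 to 0.472 between knockdown and human Setx changes, and -0.00511 to 0.206 and -0.0746 to 0.207 between conditions, the negative values being reversals; the cause was not tested.

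Lists called numbered 0 with an estimated correlation in the knockdown, human Setx and interaction comparisons (1, 5, 7, 5, 7 and 3 with the preset one) and 1 in each retinoic acid comparison (5, 10 and 10). With fry they numbered 0 and 1 for knockdown cells, 0 for human Setx cells in both conditions, 3 and 4 for retinoic acid in control and human Setx cells, and 1 and 0 for the interactions. Quantile normalization gave 0 and 2 for knockdown cells, and the mean of all probesets of a gene left every number of lists as it was.

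Replicate numbers are shared between groups, but each comparison has only 2 pairs and the labels name no shared culture or day, so the numbers were not taken to pair the samples. Deviations of same-numbered samples correlated from -0.0746 to 0.471 between groups, and between the conditions of a line at 0.471 in control, 0.442 in human Setx and 0.264 in knockdown cells, as a hint from the data and not the design. In control cells the Y-linked genes named above were low in replicate 2 in both conditions, so same-numbered control samples shared that state. The reported fit leaves such shared differences in the spread. With a replicate block 2839 and 3367 probesets passed in knockdown cells, 2 and 2 in human Setx cells, 2798, 2284 and 2395 with retinoic acid, and 114 and 0 in the interactions, and 9 lists passed for retinoic acid in control cells and 5 in the human Setx interaction. With a replicate block within each line 3884, 3032 and 3368 probesets passed with retinoic acid in control, knockdown and human Setx cells, and 222 and 0 in the interactions. The planned check of the Setx level was not run. Signal over background was not given, so its limit was not assessed.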

Other observations

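The tests on Y-linked genes in control replicate 2 and the choice of genes that separate the control replicates were made only after the results were seen.

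Imprinted and X-linked genes were among those that set the control replicates apart. Igf2r, an imprinted receptor gene, stood at 7.14 in control replicate 1 and 9.84 in control replicate 2 without retinoic acid, and at 7.64 and 10.7 with it, while it lay between 6.11 and 6.91 in all samples of the other lines. Meg3 lay between 7.92 and 8.89 in knockdown samples and between 6.21 and 6.47 in human Setx samples, and its imprinted neighbour Dlk1 was 1.44 and 1.75 log2 units higher in control replicate 2 than in control replicate 1. Nanog, a pluripotency factor, stood at 11.8 in control replicate 1 and 7.54 in control replicate 2 with retinoic acid. Tspan6 (-3.88 and -5.03 log2 units for replicate 1 minus replicate 2 without and with retinoic acid), Mgst1 (-2.72 and -3.67) and the caudal homeobox gene Cdx2 (3.02 and 2.57) separated the control replicates too. None of these differences between single samples was tested.

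A candidate explanation is that control replicate 2 came from a separate subline without Y-linked transcripts. Of 9 Y-linked genes measured, 4 were above the array median in control replicate 1 in both conditions, and all 4 lay below the lower quartile in control replicate 2. These were the genes that raised the idea, so the count does not count for it, and no other Y-linked gene was left for a test. Whether control replicate 2 hides changes in human Setx cells also stayed open: without it 15 probesets passed without and 14 with retinoic acid, between the fewer than 10 and at least 50 set beforehand.

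Peg3 and Impact, both imprinted, were among the genes lowered most in knockdown cells, which raised the hypothesis that imprinted genes changed more often than others. Of 49 other imprinted genes 3 passed in both conditions in the same direction (6.12%), against 897 of 19887 other genes (4.51%). The odds ratio was 1.38 (95% interval 0.274 to 4.31; Fisher's exact test, two-sided p = 0.486), so neither a higher nor an equal share can be concluded. The 3 were Dcn, Airn (1.39 without and 2.07 with retinoic acid) and Peg12 (1.30 and 0.69).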
